A study of Mus musculus with 8 samples.

How the data were processed

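Dermal wound tissue of C57B6/L mice was measured with 4 long RNA libraries and 4 small RNA libraries, in each case 2 from wounds under control dressing and 2 from wounds under negative pressure wound therapy (NPWT), all taken on day 3. Groups and replicate numbers come from the sample titles. The labels do not say whether the libraries are separate mice or pools, so every p-value measures only the spread between these samples, which may in part be technical.

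Per the labels' protocols, long RNA libraries were depleted of ribosomal RNA and prepared with a directional kit for Illumina sequencing, and the small RNA libraries were sequenced on an Ion Proton. HISAT2, BWA and the genome build mm10 are named without a role in the submitters' processing notes; their versions, the counting program, its use of strand, the circular RNA caller, its filters and the miRNA annotation are not given in the sources used here. The deposited tables hold raw counts, which the authors did not normalize: whole numbers per gene symbol (44792 rows), per mature miRNA (1915 rows) and per circular RNA back-splice junction (10936 rows, of which 3823 are at 0 in all 4 libraries). Between 95.8 and 97.0% of the non-zero circular RNA counts were even, so both mates of a read pair were probably counted. These counts were used as deposited, and halved counts were tried as an alternative. All sample columns were used.

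Total counts were 13946263 to 17070108 per long RNA library, 3974533 to 8305239 per small RNA library and 16371 to 32051 back-splice counts per long RNA library. A count of 0 was given a floor of 6 counts over the group for circular RNAs (3 read pairs). At the smallest totals 3 counts came to 0.215 CPM in long RNA and 0.755 CPM in small RNA. Reads carried no molecular identifiers, so floors cover counting error only.

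Each table was tested on its own with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, two-sided, group as the only term, trimmed mean of M-values (TMM) scaling, Benjamini-Hochberg adjustment, threshold 0.05). Long RNA genes and miRNAs were filtered with filterByExpr. Circular RNAs needed at least 2 counts in at least 2 libraries and at least 10 counts in all. Library sizes were the totals of the features tested. Fold changes are given on the log2 scale with a standard error (SE) taken as the fold change divided by the root of the F statistic. Circular RNAs were also tested against the linear RNA of the host gene named in the table, in a model with a term per library, a term for the kind of RNA and their interaction with group, where the host had at least 20 counts. The circular RNA yield was compared with an exact permutation test, whose smallest possible p for 2 against 2 libraries is 0.3333; circular RNAs detected were counted after thinning each library to 16371 counts in 20 draws.

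There were 40 gene lists for long RNA and 9 for small RNA, tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01 where at least 4 members were tested. Of the long RNA members, 671 matched by symbol, 12 by an older symbol of the reference table, and 22 were not matched; these include every member of the mitochondrially encoded list, which is not analysed here. Of the small RNA members 104 matched and 1 did not. Of the 668 long RNA list genes in the table, 15 were in more than 1 list. The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. For each table the rule named the 8 largest rises and 8 largest falls among features with an adjusted p under 0.05 whose NPWT libraries both lay above or both below the controls, leaving out long RNA genes under a mean of 1 CPM and predicted genes. Where fewer than 3 passed in a direction, the 5 with the smallest unadjusted p were named as not passing. From each list it took up to 4 passing members, or otherwise the 2 with the highest mean CPM. For circular RNA against host it took the 3 with the smallest p. A gene that the rule names is not reported here.

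Junction ends were placed in protein-coding genes with the RefSeq table of assembly GRCm38.p6, the assembly of mm10. Genes were called one family when the leading letters of their symbols matched. Coordinates are 1-based.

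The procedures were tested on simulated data with the tables' own means, library sizes and fitted spread, in 5 draws of 200 changed features each. Of long RNA genes changed 8-fold, edgeR called 73.6% (4-fold 44.8%, 2-fold 2.69%) over 17104 genes. Of miRNAs changed 8-fold it called 99.4% (4-fold 91.3%, 2-fold 35.5%) over 802 miRNAs. Of circular RNAs changed 8-fold it called 0.311% over 919 circular RNAs, and 0% at 2-fold or 4-fold. Against host RNA it called 0% at each of these sizes over 923 circular RNAs. Of 50 simulated long RNA lists of 20 genes moved 2-fold, camera called 50 with the preset correlation and 0 with an estimated correlation. With the preset correlation it called 1 of 145 unmoved lists. Simulated genes were drawn independently of each other, so these rates do not cover lists whose members vary together. The correlation estimated from the data was 0.425 for neutrophil markers and 0.898 for skeletal muscle.

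Alternatives were DESeq2 1.42.0, limma-voom, relative log expression (RLE) factors, library totals alone, no filter, a stricter filter, the replicate number as a block, leaving out each library, other thresholds, fry, an estimated correlation, and library sizes of the long RNA table for circular RNAs. A robust spread, halved counts and the removal of junctions between 2 genes were added after seeing the data.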

Results

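The series compares negative pressure wound therapy (NPWT), in which a sealed wound is kept under suction (here -120 mmHg), with a dressing renewed daily and saline cleaning, in foam-covered scalds of 2 cm on the backs of mice inoculated with the bacterium Pseudomonas aeruginosa. Tissue from day 3 gave 2 control and 2 NPWT libraries of long RNA, which were counted both per gene and per circular RNA (circRNA), and 2 and 2 libraries of small RNA counted per miRNA. Long RNA totals were 13946263 and 15468796 counts in the control libraries and 14016292 and 17070108 in the NPWT libraries. Small RNA totals were 8305239 and 3974533 in the controls and 6082419 and 8146806 under NPWT. Libraries of one group correlated across genes (log2 CPM) at r = 0.949 in the controls and 0.938 under NPWT for long RNA, and at 0.984 and 0.986 for miRNAs. Across groups r ran from 0.901 to 0.953 for long RNA and from 0.964 to 0.977 for miRNAs. For circRNAs r was 0.362 in the controls, 0.203 under NPWT and 0.113 to 0.36 across groups.

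In long RNA the wounds under NPWT held more RNA of neutrophil, cytokine and interferon-response genes and less of skeletal muscle and of differentiated epidermis, by camera with a preset correlation. None of these list calls held with an estimated correlation (camera adjusted p from 0.576 to 0.65). Nos2, the inducible nitric oxide synthase, rose from 7.96 and 8.47 CPM in the control libraries to 406 and 468 CPM under NPWT (log2 fold change 5.73 ± 0.30 SE, n = 2 per group, edgeR adjusted p = 0.0244). Nos2 was the only gene of 17104 to pass, with 1 higher and 0 lower; 2278 genes had an unadjusted p under 0.05, of which 1330 were higher and 948 lower. DESeq2 called 944 genes (658 higher and 286 lower) and limma-voom called 1. Both NPWT libraries lay above or both below the controls for 46.6% of the genes, where chance gives 33.3%. Genes vary together, so such a share can exceed 33.3% without an effect of the group. The edgeR call of Nos2 was lost without control 1 (adjusted p = 0.0965, log2 fold change 5.69) and without control 2 (adjusted p = 0.518, log2 fold change 5.79). Without NPWT 1 the count of called genes was 228, and without NPWT 2 it was 20.

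The genes with the next smallest p-values did not pass in edgeR. On the higher side, Timp1, an inhibitor of matrix metalloproteinases, stood at 22.4 and 21.7 CPM in the controls and at 267 and 235 CPM under NPWT (log2 fold change 3.51 ± 0.25 SE, edgeR adjusted p = 0.0764). Arg1, the arginase of alternatively activated macrophages, had a log2 fold change of 4.70 ± 0.42 SE and the interferon-induced Ifitm1 one of 2.86 ± 0.26 (edgeR adjusted p = 0.126 for each). On the lower side Krt77, a keratin of differentiated epidermis, stood at 500.0 and 613 CPM against 34.6 and 67.9 CPM (log2 fold change -3.44 ± 0.42 SE). The epidermal Flg2 and Lce1m had log2 fold changes of -2.53 ± 0.28 and -2.26 ± 0.30, Skint5, of a gene family expressed in skin and thymus, -2.70 ± 0.31, and Ppp1r3c, a regulator of glycogen synthesis, -2.17 ± 0.28 (edgeR adjusted p = 0.126 for each). All 8 of these genes were called by DESeq2.

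**Figure D1:**
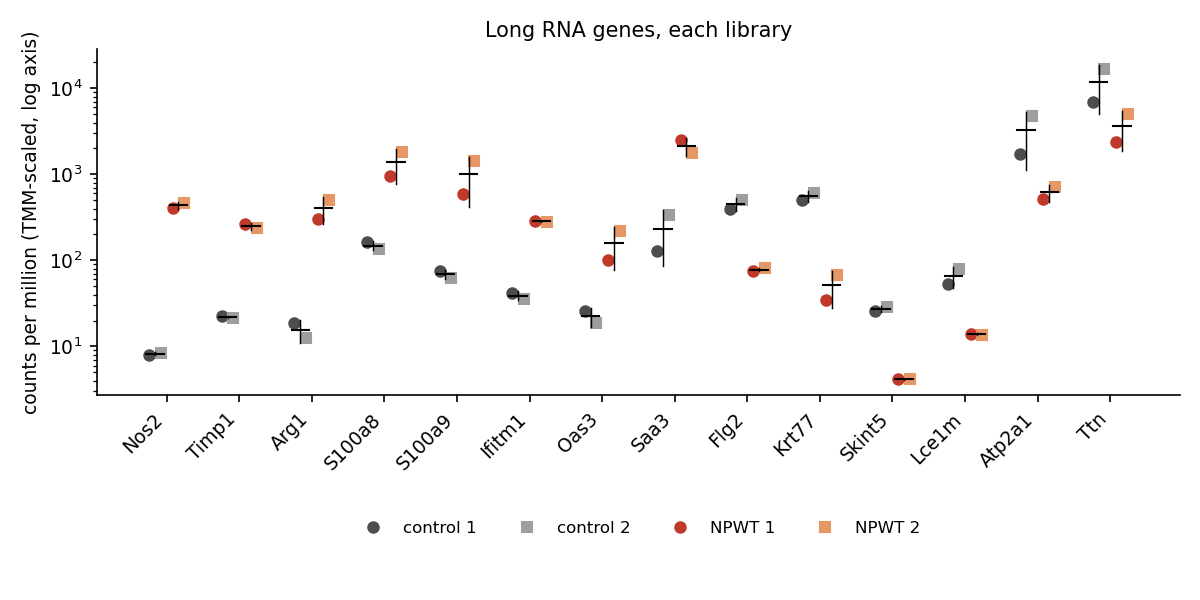
Long RNA genes in each library, as TMM-scaled CPM on a log axis. Grey points are the 2 control libraries and coloured points the 2 NPWT libraries; horizontal bars are group means and vertical bars their SD (n = 2). Nos2 stands at 7.96 and 8.47 CPM in the controls and at 406 and 468 CPM under NPWT.

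Of the 39 gene lists tested in long RNA, limma's camera called 20 with the preset correlation, 12 up and 8 down, and none with an estimated correlation. Apart from Nos2, no member of a list passed in edgeR when adjusted over all genes tested; all counts of members here are from edgeR unless DESeq2 is named. Neutrophil markers rose (median log2 fold change 3.24, all 17 tested members higher in both NPWT libraries than in both controls, camera adjusted p = 1.42e-35; adjusted p = 0.576 with an estimated correlation). Adjusted over the list alone, 15 of the 17 passed in edgeR, and 0 over all genes tested, where DESeq2 called 15. S100a8 and S100a9, the calprotectin subunits, had log2 fold changes of 3.21 ± 0.43 and 3.86 ± 0.51 SE. S100a8 measured 162 and 136 CPM in the controls and 953 and 1808 CPM under NPWT. Inflammatory cytokines and chemokines rose (median 2.96, camera adjusted p = 1.94e-18; adjusted p = 0.576 with an estimated correlation), with 15 of 20 passing adjusted over the list alone and 1, Nos2, over all genes tested (DESeq2 13). The interferon response list rose (median 1.48, camera adjusted p = 4.01e-21; adjusted p = 0.576 with an estimated correlation), with 22 of 26 passing adjusted over the list alone and 0 over all genes tested (DESeq2 15). Among its members Oas3, an oligoadenylate synthetase, had a log2 fold change of 2.84 ± 0.44 SE and the transcription factor Stat2 one of 0.85 ± 0.24. Antimicrobial peptides and proteins rose (median 1.86, camera adjusted p = 3.67e-14; adjusted p = 0.576 with an estimated correlation), 11 of 19 passing adjusted over the list alone and 0 over all genes tested (DESeq2 10). Saa3, an acute phase serum amyloid A that is also on the acute phase list, stood at 129 and 339 CPM in the controls and at 2479 and 1768 CPM under NPWT (log2 fold change 3.18 ± 0.56 SE). Of the neutrophil markers, Camp, Ltf, S100a8 and S100a9 are also on the antimicrobial list, and Mmp8 and Mmp9 on the protease list below. The rises of those lists are therefore not independent of the neutrophil rise.

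Monocyte and macrophage markers rose (median 1.16, camera adjusted p = 3.56e-09; adjusted p = 0.576 with an estimated correlation), with 10 of 18 passing adjusted over the list alone. The macrophage pore protein gene Mpeg1 had a log2 fold change of 1.91 ± 0.28 SE and the lysozyme gene Lyz2 one of 1.25 ± 0.53, or 1.90 without control 1, 0.81 without control 2 and 0.64 without NPWT 1. Toll-like receptor and NF-kB signalling rose (median 1.00, camera adjusted p = 5.14e-09; adjusted p = 0.576 with an estimated correlation), with 5 of 24 passing adjusted over the list alone; the lipopolysaccharide co-receptor gene Cd14 had a log2 fold change of 3.61 ± 1.15 SE and the NF-kB inhibitor gene Nfkbia 1.57 ± 0.75. Without NPWT 2 these came to 1.10 for Cd14 and 0.51 for Nfkbia, which stood at 0.94 without control 1 and 2.74 without control 2. Acute phase and complement genes rose (median 0.90, camera adjusted p = 2.14e-05; adjusted p = 0.683 with an estimated correlation), with 4 of 15 passing adjusted over the list alone, though the complement gene C4b had a log2 fold change of 0.10 ± 0.34 SE. Collagens and matrix genes rose (median 0.53, camera adjusted p = 0.000433; adjusted p = 0.576 with an estimated correlation), with 0 of 28 passing adjusted over the list alone; Col3a1 had a log2 fold change of 1.37 ± 0.58 SE and Col1a1 0.55 ± 0.59. Without control 1 these came to 2.21 and 1.45, and without control 2 to 0.85 and 0.02. For each of these 4 lists 0 members passed in edgeR over all genes tested, where DESeq2 called 8, 6, 5 and 1.

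The muscle and epidermis lists fell. Skeletal muscle genes had a median log2 fold change of -1.41 with all 22 members lower (camera adjusted p = 1.83e-13; adjusted p = 0.65 with an estimated correlation), and 9 passed adjusted over the list alone. Titin (Ttn) stood at 7013 and 16647 CPM in the controls and at 2399 and 4961 CPM under NPWT, and the calcium pump gene Atp2a1 had a log2 fold change of -2.40 ± 0.56 SE, or -1.49 without control 2. Differentiated epidermis genes fell (median -0.60, camera adjusted p = 1.29e-07; adjusted p = 0.576 with an estimated correlation), with 4 of 21 passing adjusted over the list alone. The abundant suprabasal keratins Krt1 and Krt10 had log2 fold changes of 0.12 ± 0.38 and -0.12 ± 0.35 SE. In both lists 0 members passed in edgeR over all genes tested, where DESeq2 called 11 muscle and 4 epidermis genes, all lower. All 10 lists described so far were called again without each library in turn, but leaving out 1 library moved several medians by over 1.5 times. Without control 1 the collagen median was 0.89. Without control 2 the antimicrobial median was 2.95 and the skeletal muscle median -0.71. Without NPWT 1 the acute phase median was 0.34, and without NPWT 2 the cytokine and Toll-like receptor medians were 1.42 and 0.59.

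The other 10 called lists were each lost without at least 1 library, and 0 of their members passed in edgeR over all genes tested. DESeq2 called 5 protease genes, 3 hypoxia genes, 2 sebaceous genes and 1 gene each of the adipocyte, basal keratinocyte, pericyte and B cell lists, and 0 of the nerve, oxidative phosphorylation and cell cycle lists. Sebaceous gland genes fell (median -1.10, camera adjusted p = 0.00286; adjusted p = 0.69 with an estimated correlation; 0 of 12 adjusted over the list alone), but without control 2 the median was -0.22 (adjusted p = 0.175). In that list the desaturase gene Scd1 stood at 3933 and 17604 CPM in the controls and at 4624 and 2265 CPM under NPWT, and Soat1 had a log2 fold change of 0.22 ± 0.28 SE. Adipocyte markers fell (median -0.70, camera adjusted p = 0.00999; adjusted p = 0.733 with an estimated correlation; 0 of 17 adjusted over the list alone), with medians of 0.21 without control 2 (adjusted p = 0.82) and -0.13 without NPWT 2 (adjusted p = 0.978). Car3 had a log2 fold change of -1.58 ± 0.56 SE, and Cd36, a fatty acid transporter, -1.61 ± 0.83, or -0.80 and -0.0016 without control 2. Basal keratinocyte markers fell (median -0.65, camera adjusted p = 0.00385; adjusted p = 0.69 with an estimated correlation; 1 of 11 adjusted over the list alone), with a median of -0.33 without NPWT 1 (adjusted p = 0.288), while Krt14 and Krt5 had log2 fold changes of 0.30 ± 0.49 and -0.47 ± 0.41 SE. Nerve and Schwann cell markers fell (median -0.48, camera adjusted p = 0.0273; adjusted p = 0.69 with an estimated correlation; 0 of 14 adjusted over the list alone), with medians of -0.11 without control 2 (adjusted p = 0.44) and -0.67 without NPWT 1 (adjusted p = 0.163). Among them Erbb3 had a log2 fold change of -1.24 ± 0.37 SE, or -0.70 without control 2, and the myelin gene Pmp22 -0.28 ± 0.29.

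Nuclear genes of oxidative phosphorylation fell (median -0.28, camera adjusted p = 0.0316; adjusted p = 0.734 with an estimated correlation; 0 of 23 adjusted over the list alone), with medians of -0.13 without control 2 (adjusted p = 0.44) and -0.35 without NPWT 1 (adjusted p = 0.159); the ATP synthase genes Atp5a1 and Atp5b had log2 fold changes of -0.39 ± 0.29 and -0.37 ± 0.28 SE. Pericyte and smooth muscle genes fell (median -0.32, camera adjusted p = 0.0406; adjusted p = 0.606 with an estimated correlation; 0 of 12 adjusted over the list alone), though Des and Notch3 had log2 fold changes of -0.09 ± 0.57 and 0.06 ± 0.26 SE. That call was lost without control 1 (adjusted p = 0.054, median -0.62), control 2 (0.112, median -0.35) and NPWT 2 (0.0964, median -0.21). Proteases and inhibitors of matrix turnover rose (median 0.43, camera adjusted p = 0.00385; adjusted p = 0.576 with an estimated correlation; 7 of 23 adjusted over the list alone), but without NPWT 2 the median was -0.21 (adjusted p = 0.137), and the gelatinase gene Mmp2 and its activator Mmp14 had log2 fold changes of -0.34 ± 0.29 and -0.06 ± 0.30 SE. Hypoxia and glycolysis genes rose (median 0.43, camera adjusted p = 0.0175; adjusted p = 0.733 with an estimated correlation; 2 of 23 adjusted over the list alone), with medians of 0.13 without control 1 (adjusted p = 0.991) and 0.30 without NPWT 2 (adjusted p = 0.219). The glycolytic Pkm and Aldoa had log2 fold changes of 0.59 ± 0.39 and -0.24 ± 0.41 SE. Cell cycle genes rose (median 0.34, camera adjusted p = 0.0388; adjusted p = 0.778 with an estimated correlation; 0 of 24 adjusted over the list alone), with medians of -0.003 without control 2 (adjusted p = 0.82) and 0.25 without NPWT 1 (adjusted p = 0.409). This was the only called list also lost with library totals only (median 0.27, camera adjusted p = 0.0532); Mki67 and Top2a had log2 fold changes of 0.42 ± 0.39 and 0.11 ± 0.39 SE. The 4 tested B cell markers rose (median 0.85, camera adjusted p = 0.0406; adjusted p = 0.69 with an estimated correlation), with medians of 0.51 without control 2 (adjusted p = 0.33) and -0.18 without NPWT 1 (adjusted p = 0.519). Of these the inhibitory receptor gene Cd22 passed adjusted over the list alone, at 0.855 and 0.752 CPM in the controls and 6.35 and 4.47 CPM under NPWT, while the immunoglobulin gene Ighm had a log2 fold change of 0.71 ± 0.74 SE.

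**Figure D2:**
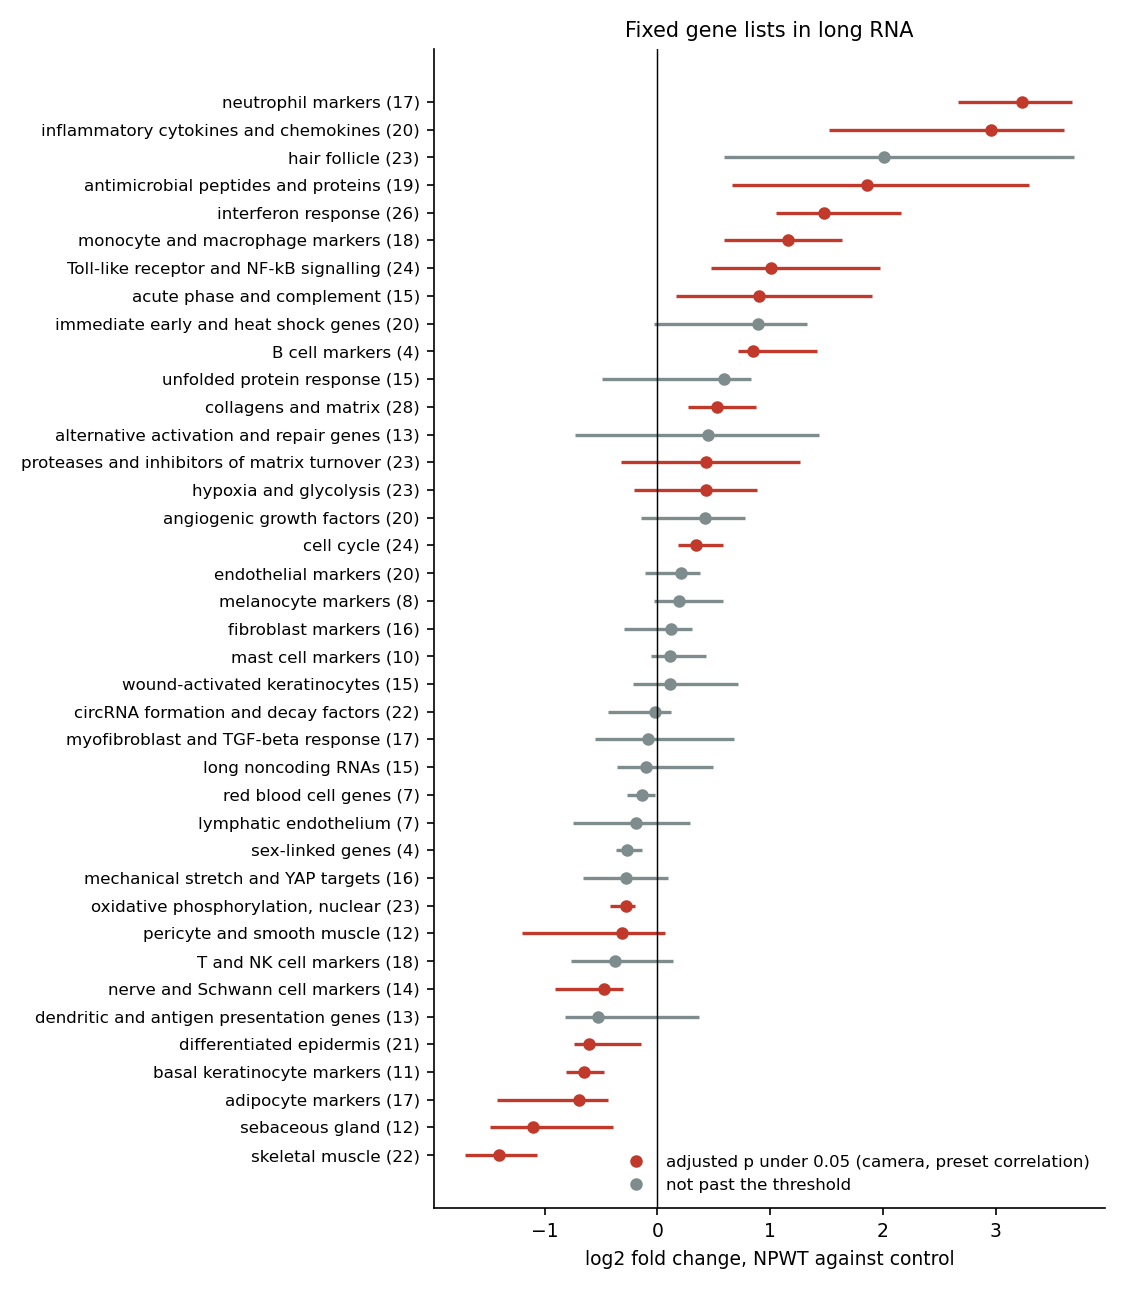
Log2 fold change of NPWT against control for the 39 gene lists of long RNA; each dot is the median of a list's members, each line spans their quartiles, and the number of members tested is in brackets. Red lists had an adjusted p under 0.05 in camera with the preset correlation, and neutrophil markers (median 3.24) and skeletal muscle (median -1.41) stand at the ends.

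For 19 lists camera gave no call. Hair follicle genes had a median log2 fold change of 2.01 (camera adjusted p = 0.144, 0 of 23 adjusted over the list alone) without a split by group: the root sheath keratin gene Krt71 stood at 352 and 3.55 CPM in controls 1 and 2 and at 1117 and 1.32 CPM in NPWT 1 and 2, and Tchh had a log2 fold change of 2.76 ± 1.92 SE. Alternative activation and repair genes moved both ways (median 0.45, camera adjusted p = 0.0857), and 9 of 13 passed adjusted over the list alone, 6 higher and 3 lower; the receptor gene Il4ra had a log2 fold change of 1.06 ± 0.36 SE (0.69 without NPWT 2) and Gpnmb -0.17 ± 0.28. Dendritic and antigen presentation genes had a median of -0.53 (camera adjusted p = 0.0597), with Cd74 at -0.53 ± 0.25 SE and H2-Aa at -0.82 ± 0.31. Wound-activated keratinocyte genes had a median of 0.11 (camera adjusted p = 0.0957, 1 of 15 adjusted over the list alone), with the wound keratins Krt6a at 0.03 ± 0.36 SE and Krt6b at 0.39 ± 0.40. Immediate early and heat shock genes had a median of 0.89 (camera adjusted p = 0.0957), with Dusp1 at 1.17 ± 1.01 SE and Junb at 2.30 ± 0.82, or -0.48 and 0.49 without NPWT 2. T and NK cell markers had a median of -0.38 (camera adjusted p = 0.14), with Il2rb at -0.20 ± 0.44 SE and Trbc2 at -0.31 ± 0.36. Angiogenic growth factors had a median of 0.42 (camera adjusted p = 0.144), with the chemokine Cxcl12 at 1.29 ± 0.34 SE and Angptl4 at -0.14 ± 0.83. Endothelial markers had a median of 0.21 (camera adjusted p = 0.264), with Pecam1 at 0.25 ± 0.31 SE and Vwf at 0.11 ± 0.24. Lymphatic endothelium markers had a median of -0.19 (camera adjusted p = 0.236), with Lyve1 at -1.77 ± 0.38 SE and Pdpn at 0.95 ± 0.49. Pdpn came to 1.44 without control 1, 0.60 without control 2 and 0.23 without NPWT 2. Lyve1 passed adjusted over the list alone. In the 16 lists without a call other than the lymphatic, alternative activation and wound-activated keratinocyte lists, 0 members did. DESeq2 called 8 alternative activation genes and 3 each of the immediate early and myofibroblast lists. It called 2 each of the wound-activated keratinocyte, T and NK cell and angiogenic lists. It called 1 each of the lymphatic, hair follicle and long noncoding RNA lists, and 0 in every other list without a call.

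Among the remaining lists without a call, fibroblast markers had a median log2 fold change of 0.12 (camera adjusted p = 0.898), with Dcn at -0.07 ± 0.32 SE and Lum at 0.18 ± 0.37. Myofibroblast and TGF-beta response genes had a median of -0.08 (camera adjusted p = 0.997), with Tgfbi at 0.68 ± 0.33 SE and Tgfbr2 at -0.55 ± 0.29. Mechanical stretch and YAP targets had a median of -0.28 (camera adjusted p = 0.176), with Axl at -0.49 ± 0.29 SE and Tead1 at -1.03 ± 0.38, or -0.45 without control 2. Unfolded protein response genes had a median of 0.59 (camera adjusted p = 0.279), with the chaperone genes Calr at 0.84 ± 0.36 SE and Hspa5 at 0.73 ± 0.35. Genes for circRNA formation and decay had a median of -0.02 (camera adjusted p = 0.351), with the splicing regulators Qk at -0.54 ± 0.38 SE and Mbnl1 at -0.45 ± 0.29. Qk came to -0.89 without control 1 and -0.07 without control 2. Mbnl1 came to -0.67 without NPWT 1 and -0.25 without NPWT 2. Mast cell markers (median 0.11, camera adjusted p = 0.75) held Mcpt4 at 0.25 ± 0.24 SE and Tpsb2 at 0.10 ± 0.32. Red blood cell genes (median -0.13, camera adjusted p = 0.475) held Hbb-bs at -0.06 ± 0.44 SE and Hba-a1 at 0.01 ± 0.25, whose near-identical copies can share reads. Melanocyte markers (median 0.19, camera adjusted p = 0.997, direction down) held Dct at -0.11 ± 0.84 SE and Pmel at 0.00 ± 1.18. Long noncoding RNAs (median -0.10, camera adjusted p = 0.964, direction up) held Malat1 at 0.10 ± 0.44 SE and Neat1 at 0.49 ± 0.44. Sex-linked genes (median -0.27, camera adjusted p = 0.421) held Uty at -0.50 ± 0.29 SE and Eif2s3y at -0.22 ± 0.26.

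In small RNA, several miRNAs known from myeloid cells rose under NPWT. The neutrophil and monocyte miRNA miR-223-3p rose from 23363 and 33022 CPM in the controls to 88240 and 196630 CPM under NPWT (log2 fold change 2.34 ± 0.37 SE, n = 2 per group, edgeR adjusted p = 0.00317), and its other arm miR-223-5p by 2.12 ± 0.40 (edgeR adjusted p = 0.00625). The macrophage-inducible miR-147-3p rose from 69.0 and 60.2 CPM to 361 and 522 CPM (log2 fold change 2.77 ± 0.32 SE, edgeR adjusted p = 0.000229) and miR-147-5p rose by 2.59 ± 0.44 (edgeR adjusted p = 0.00317). The blood cell miRNA miR-142a-3p rose by 2.03 ± 0.34 (edgeR adjusted p = 0.00317). Of 802 miRNAs tested, edgeR called 96, 73 higher and 23 lower, and 197 had an unadjusted p under 0.05. Both NPWT libraries lay above or both below the controls for 54.2% of the tested miRNAs, where chance gives 33.3%, though miRNAs vary together. The count was 33 without control 1, 85 without control 2, 107 without NPWT 1 and 65 without NPWT 2. Scaled by library totals alone, 49 were higher and 33 lower, and the median of all miRNAs shifted by -0.15 on the log2 scale.

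The largest rise was that of miR-291a-5p, a miRNA of embryonic stem cells, at low levels (0.24 and 0.685 CPM in the controls, 3.46 and 4.13 CPM under NPWT; log2 fold change 3.17 ± 0.72 SE, edgeR adjusted p = 0.0149). Among the 8 largest rises were also miR-129b-3p (2.68 ± 0.80, or 1.54 without control 1 and 4.86 without control 2), miR-129-5p (2.61 ± 0.60), miR-466e-3p (2.53 ± 0.59) and miR-669b-5p (2.32 ± 0.42). The last pair belong to families of near-identical copies that can share reads, so their single values are uncertain. Control counts were also low, at 1 and 6 for miR-129b-3p, 6 and 6 for miR-129-5p and 13 and 4 for miR-466e-3p. Of 59 arms tested in the families miR-297, miR-466, miR-467 and miR-669, 31 were called higher and 0 lower. These arms were thus 31 of the 73 miRNAs called higher. The largest falls were those of miR-3063-5p (log2 fold change -2.48 ± 0.62 SE), miR-5131 (-2.29 ± 0.38), miR-762 (-2.13 ± 0.38), miR-7035-5p (-1.79 ± 0.42), miR-8093 (-1.74 ± 0.54), miR-1224-3p (-1.74 ± 0.48, or -1.10 without control 1), miR-7686-5p (-1.70 ± 0.48) and miR-1957b (-1.55 ± 0.39). Several of these rest on low counts. The counts of miR-3063-5p were 43 and 14 in the controls and 5 and 5 under NPWT, near the floor. Under NPWT miR-8093 had 10 and 9 counts, miR-7686-5p 12 and 16, and miR-1224-3p 16 and 17. Of the 22 called miRNAs named here, 8 stayed past the threshold without each library in turn: both arms of miR-147 and miR-223, miR-142a-3p, miR-669b-5p, miR-5131 and miR-762. Without control 1, the calls of 12 were lost (edgeR adjusted p from 0.0723 to 0.497): miR-291a-5p, miR-129b-3p, miR-129-5p, miR-3063-5p, miR-7035-5p, miR-8093, miR-1224-3p, miR-7686-5p, miR-1957b, miR-543-3p, miR-451a and miR-144-5p. Without control 2, the calls of 5 were lost (edgeR adjusted p from 0.0608 to 0.134): miR-8093, miR-7686-5p, miR-1957b, miR-144-3p and miR-451a. Without NPWT 1, those of miR-8093 and miR-7686-5p were lost (edgeR adjusted p = 0.0888 and 0.0976). Without NPWT 2, the calls of 11 were lost (edgeR adjusted p from 0.0533 to 0.264): miR-291a-5p, miR-129b-3p, miR-129-5p, miR-466e-3p, miR-3063-5p, miR-8093, miR-1224-3p, miR-7686-5p, miR-144-3p, miR-451a and miR-144-5p. With library totals only, miR-129b-3p and miR-144-5p were lost (edgeR adjusted p = 0.0621 and 0.0574), and with limma-voom miR-8093 was lost (adjusted p = 0.0615). DESeq2 gave no adjusted p to miR-291a-5p, miR-129b-3p, miR-3063-5p and miR-8093.

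Of the 9 miRNA lists, camera called 1. Myeloid and inflammation miRNAs rose (median log2 fold change 0.94, camera adjusted p = 1.33e-05; adjusted p = 0.313 with an estimated correlation), with 13 of 17 passing adjusted over the list alone, 11 higher and 2 lower (miR-124-3p and miR-187-3p), and 9 over all miRNAs tested, all higher. Epithelial miRNAs had a median of -0.50 (camera adjusted p = 0.0512), with the keratinocyte miRNAs miR-203-3p at -0.44 ± 0.27 SE and miR-205-5p at -0.50 ± 0.29. Erythroid miRNAs had a median of 0.48 (camera adjusted p = 0.163), and 3 of 6 passed over all miRNAs tested and adjusted over the list alone: miR-144-3p (1.33 ± 0.33), miR-144-5p (1.13 ± 0.29) and miR-451a (1.05 ± 0.27). The list of miR-29 and fibrosis miRNAs had a median of -0.31 (camera adjusted p = 0.163), with the smooth muscle miRNA miR-145a-5p at -0.67 ± 0.27 SE and miR-214-3p at 0.01 ± 0.29. Endothelial and hypoxia miRNAs had a median of 0.49 (camera adjusted p = 0.229), with miR-126a-3p at -0.09 ± 0.27 SE and miR-126a-5p at -0.03 ± 0.27. Muscle miRNAs had a median of -0.32 (camera adjusted p = 0.229), with miR-1a-3p at -0.55 ± 0.32 SE and miR-133a-3p at -0.41 ± 0.32. Lymphocyte miRNAs had a median of 0.25 (camera adjusted p = 0.53), and their 1 member that passed, miR-142a-3p, is also on the myeloid list. The let-7 family had a median of -0.07 (camera adjusted p = 0.56), with let-7c-5p at -0.53 ± 0.28 SE and let-7a-5p at -0.23 ± 0.28. Of the Dlk1-Dio3 cluster (median 0.01, camera adjusted p = 0.637), 1 of 26 passed, miR-543-3p at 2.04 ± 0.44 SE. In the 5 lists without such a member 0 passed adjusted over the list alone. Among those 5 lists DESeq2 called 1 epithelial miRNA, lower, and 1 endothelial and hypoxia miRNA, higher, and 0 in the rest.

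**Figure D3:**
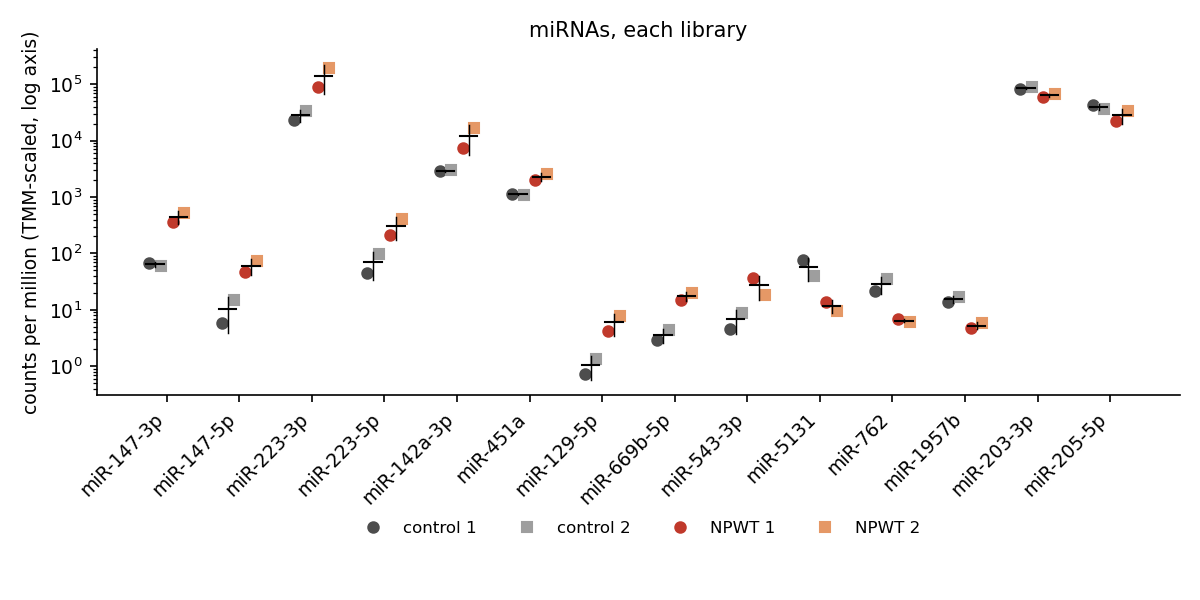
miRNAs in each small RNA library, as TMM-scaled CPM on a log axis. Grey points are the 2 control libraries and coloured points the 2 NPWT libraries; horizontal bars are group means and vertical bars their SD (n = 2). miR-223-3p stands at 23363 and 33022 CPM in the controls and at 88240 and 196630 CPM under NPWT.

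The series asks which circRNAs, RNA circles made by back-splicing, differ under NPWT. Several junctions had counts in both libraries of one group and 0 in the other, but none passed the edgeR test. Both NPWT libraries lay above or both below the controls for 35.5% of the 940 circRNAs tested, where chance gives 33.3%. Groups were thus apart about as often as chance gives. A junction of Gm5150, a predicted gene, on chromosome 3 (mm10, 15990630 to 15990986) had 94 and 68 counts under NPWT and 0 in both controls, at least 22.8-fold higher. A junction of Tmem164 on chromosome X (142832501 to 142834393) had 24 and 34 counts against 0 (at least 8.14-fold higher), one of Nptn on chromosome 9 (58640669 to 58643802) 8 and 52 against 0 (at least 8.43-fold higher), and one of the histone deacetylase gene Hdac4 on chromosome 1 (92141520 to 92148494) 8 and 28 against 0 (at least 5.06-fold higher). A junction of Depdc5 on chromosome 5 (32955853 to 32968771) had 126 and 44 counts under NPWT and 2 and 8 in the controls (log2 fold change 4.26 ± 1.23 SE). Several of these bounds rest on 1 library: that of Gm5150 was 14.3-fold without NPWT 1 and 39.5-fold without NPWT 2, and those of Nptn and Hdac4 were each 3.36-fold without NPWT 2.

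On the lower side, a junction listed under Acot2 on chromosome 12 (83990494 to 84009966) had 178 and 582 counts in the controls and 0 under NPWT, at least 150.3-fold lower. A junction listed under the keratin gene Krt16 on chromosome 11 (100204108 to 100257345) had 42 and 3140 counts in the controls and 0 under NPWT, at least 629-fold lower. Both of these join genes called one family by their symbols, Acot2 to Acot1 and Krt14 to Krt17, which may share reads. Sequences were not compared. Other such junctions had many counts in 1 library and 0 in the other of its group. Krt75 to Krt71 had 2780 counts in NPWT 1 and 0 in NPWT 2, and H2-D1 to H2-M11 had 0 and 3844. A second Krt14 to Krt17 junction had 248 counts in control 1 and 0 in control 2. The bounds for the Acot2 and Krt16 junctions do not cover such differences between libraries. Junctions of Bcl11b on chromosome 12 (107989465 to 107989830), Cdk13 on chromosome 13 (17763104 to 17772957) and Dym on chromosome 18 (75114790 to 75126919) had 20 and 22, 10 and 30, and 14 and 18 counts in the controls and 0 under NPWT (at least 8.31-fold, 7.91-fold and 6.33-fold lower). All bounds on the lower side pool both NPWT libraries and were not computed against each NPWT library alone. In NPWT 2 only 1387 circRNAs were detected, against 2342 to 2971 in the other libraries. A count of 0 in NPWT 2 is therefore weaker evidence of a fall. Without control 2 the bound for the Krt16 junction was 19.1-fold, for the Acot2 junction 80.95-fold and for the Cdk13 junction 4.55-fold, and without control 1 that for the Krt16 junction was 1099-fold. Of 940 circRNAs tested edgeR called 0, with 20 higher and 10 lower at an unadjusted p under 0.05 and a smallest adjusted p of 0.492. DESeq2 called 4 and limma-voom 6, in each case including the Gm5150 and Acot2 junctions. Over all alternatives the Gm5150 junction passed in 8, the Acot2 junction in 7 and the Krt16 junction in 3. Without NPWT 1 edgeR called 28, among them the Acot2, Krt16, Bcl11b and Cdk13 junctions, and without NPWT 2 it called 1, the Depdc5 junction.

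Against the linear RNA of the host gene, edgeR called 0 of 923 circRNAs, with 32 at an unadjusted p under 0.05; limma-voom called 0, with 93 unadjusted. The smallest p-values were those of the Acot2, Krt16 and Tmem164 junctions named above (unadjusted p = 0.00135, 0.00514 and 0.011, edgeR adjusted p = 0.701 for each). The ends of the Krt16 junction lie in Krt14 and Krt17, so the linear RNA it was set against is of a gene at neither end. The listed host was at neither end for 10 of the 19 junctions between genes of one family. Across 920 circRNAs the log2 fold changes of circRNA and host had a Spearman rho of 0.239 (permutation p = 1e-04, the smallest that 10000 permutations can give); circRNAs are not independent replicates. As CPM of the long RNA total, back-splice counts were 1174 and 2072 in the controls and 1434 and 1458 under NPWT (means 1623 ± 635 and 1446 ± 17 SD, n = 2 per group, ratio 0.891, exact permutation p = 1, two-sided). That ratio turned with the libraries used: it was 0.698 without control 1, 1.23 without control 2 and 1.02 without junctions between 2 genes. After thinning to equal totals, 2288 and 1792 circRNAs had at least 2 counts in the controls and 1957 and 1271 under NPWT (exact permutation p = 0.667, where 0.3333 is the smallest possible). The long RNA library NPWT 2 stood apart here: it had 134 circRNAs at exactly 2 counts, against 1017 to 1143 in the other 3 libraries.

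**Figure D4:**
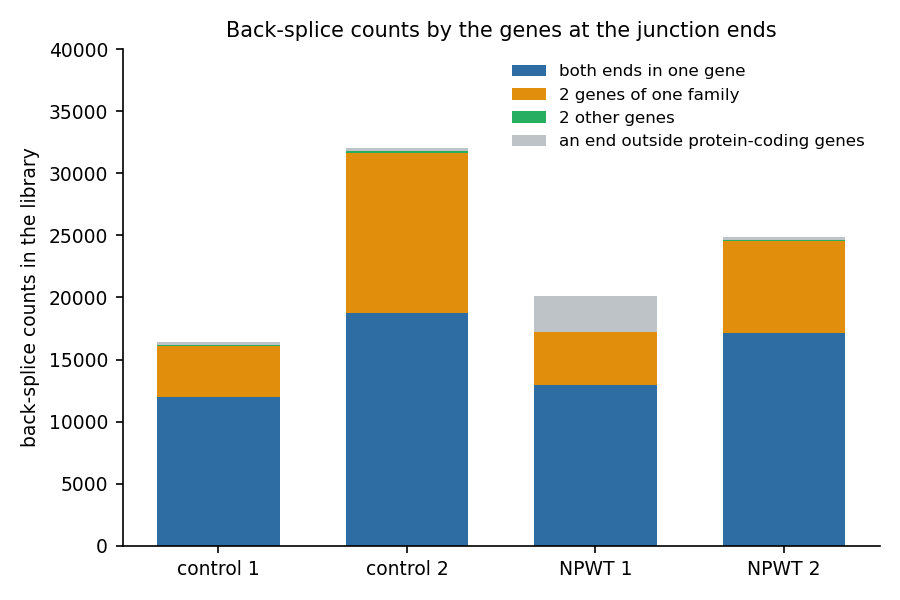
Back-splice counts in each long RNA library, stacked by whether both junction ends lie in one protein-coding gene, in 2 genes of one family, in 2 other genes, or have an end outside such genes. Junctions between 2 genes of one family hold 25.4, 40.5, 21.2 and 29.8% of the counts in control 1, control 2, NPWT 1 and NPWT 2.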

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

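The robust spread, the halved circRNA counts and the removal of junctions between 2 genes were chosen after seeing the data. The count of 1 long RNA gene became 944 with DESeq2, 7 with library totals only, 1173 with no filter on low counts, 369 with the replicate number as a replicate block and 2 at an adjusted p under 0.1, and ran from 0 to 228 over the fits without each replicate in turn. The labels give the replicate numbers no meaning that pairs samples, and 2 pairs are too few to settle it from the data: deviations of samples with one number correlated at 0.241 across long RNA genes, 0.0781 across circRNAs and -0.058 across miRNAs. The count of 0 circRNAs became 4 with DESeq2, 6 with limma-voom, 2 with RLE factors, 8 with no filter on low counts, 6 with the replicate block, 3 with the library sizes of the long RNA table, 2 with counts halved and 1 without junctions between 2 genes, and ran from 0 to 28 without each replicate. The count of 96 miRNAs became 44 with the replicate block, where of those named miR-129b-3p, miR-144-3p, miR-144-5p, miR-451a, miR-1224-3p, miR-7686-5p and miR-8093 were lost (edgeR adjusted p from 0.0565 to 0.0746), and ran from 33 to 107 without each replicate. Called lists fell from 20 to 0 in long RNA and from 1 to 0 in small RNA with an estimated correlation, and likewise to 0 and 0 with fry. Called miRNA lists came to 2 with library totals only and ran from 1 to 3 without each replicate. For all of these moves and for the changes of sign the cause was not tested. Where a replicate was left out, the lone sample of its group was assumed to vary like the other group. Library totals only shifted the median log2 fold change by 0.54 for circRNAs and by -0.15 for miRNAs. Of 1007 values of named long RNA genes under alternatives 876 kept direction and side of the threshold. So did 322 of 375 for miRNAs, 97 of 118 for circRNAs and 107 of 168 for lists. Only Nos2 of the named long RNA genes, and 0 circRNAs, had passed in edgeR. For the rest of both, keeping the side meant staying uncalled, which does not show a stable size. Leaving out 1 library turned or moved 62 of 84 named long RNA genes by more than the ratio used for list medians. These included 16 of the 34 genes with a log2 fold change of at least 1 in size, of which 3 turned. Depth and spread limit the circRNA tests, where simulated 8-fold changes were called in 0.311% of circRNAs, and in 0% against host RNA.

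Changes of sign were as follows, as log2 fold changes. With limma-voom Angptl4 came to 0.50, Pmel to -0.345 and Hba-a1 to -0.0027. With library totals only Pmel came to -0.061, Notch3 to -0.0016, Hba-a1 to -0.037, Krt6a to -0.0485 and miR-214-3p to -0.16. With the replicate block Angptl4 came to 0.49, Pmel to -0.27 and Hba-a1 to -9e-04, and with no filter miR-126a-5p to 0.0087. Ranges over the fits without each replicate that crossed 0 were Pecam1 -0.052 to 0.63, Malat1 -0.046 to 0.28, Dct -1.34 to 1.39, Mmp14 -0.19 to 0.084, Angptl4 -0.97 to 2.01, Mki67 -0.031 to 1.10, Top2a -0.33 to 0.76, Krt1 -0.24 to 0.40, Dcn -0.21 to 0.096, Lum -0.16 to 0.64, Aldoa -0.59 to 0.23, Pmel -2.59 to 1.92, Des -1.08 to 0.48, Notch3 -0.11 to 0.27, Hba-a1 -0.21 to 0.20, Eif2s3y -0.44 to 0.051, Il2rb -0.71 to 0.28, Krt6a -0.31 to 0.31, C4b -0.22 to 0.37, Ighm -0.27 to 1.96, Krt10 -0.49 to 0.17, Krt71 -7.08 to 7.30, Tchh -2.79 to 5.89, Tpsb2 -0.33 to 0.43, Gpnmb -0.43 to 0.047, Krt14 -0.43 to 0.77, Dusp1 -0.48 to 3.00, Neat1 -0.15 to 0.92, Hbb-bs -0.85 to 0.45, Krt6b -0.068 to 0.73. For miRNAs they were miR-126a-3p -0.27 to 0.17, miR-126a-5p -0.18 to 0.20, let-7a-5p -0.42 to 0.038, miR-214-3p -0.27 to 0.43, miR-133a-3p -0.73 to 0.056. Among medians of called lists, that of the cell cycle list ran from -0.003 to 0.83, adipocyte markers from -2.08 to 0.21, B cell markers from -0.18 to 1.96, and proteases and inhibitors of matrix turnover from -0.21 to 0.56. The median of the hypoxia and glycolysis list stayed above 0 (0.13 to 0.79), but camera's direction for it turned without control replicate 1. The circRNA yield ratio of NPWT to control ran from 0.698 to 1.23 over the fits without each replicate.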

Other observations

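The tests of tissue share and of the wounds sampled, of reads shared between paralogs and of the median count in the library NPWT 2 were chosen after the result was seen, as were the genes singled out here; the tests of read-through, of depth, of mean counts and of genes holding miRNAs were chosen before.

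The gene AA467197, whose span holds miR-147, stood at 1.51 and 2.87 CPM in the controls and at 8.43 and 22.7 CPM under NPWT (log2 fold change 2.82 ± 0.63 SE, edgeR adjusted p = 0.175), beside the rise of miR-147-3p. Sfmbt2, whose intron holds the cluster of the miR-297, miR-466, miR-467 and miR-669 families, stood at 0.855 and 1.57 CPM against 3.04 and 4.66 CPM (log2 fold change 1.66 ± 0.59 SE, edgeR adjusted p = 0.323); the 59 tested arms of these families had a median log2 fold change of 1.49, or 1.32 with library totals only. A hypothesis that miRNAs may move with the genes that hold them was tested across 208 other genes holding a tested miRNA. Spearman's rho was 0.0549 (permutation p = 0.428, two-sided) and Pearson's r 0.0235. No such relation was detected across genes, which are not independent replicates. The strands of miRNA and gene were not required to match, so pairs that share no transcript can be included. A miRNA inside several genes counted for each. The test therefore cannot exclude a relation within pairs that share a transcript.

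Some genes differed widely between libraries of one group. Pdk4, a kinase that restrains glucose oxidation, stood at 82.5 CPM in control 1 and 1829 CPM in control 2, with 21.8 and 29.1 CPM under NPWT. Txnip, which restrains glucose uptake, stood at 479 and 3883 CPM in the controls and at 534 and 636 CPM under NPWT. The hair gene Tchh stood at 75.6 CPM in control 1 and 536 CPM in NPWT 1, against 4.58 and 5.85 CPM in control 2 and NPWT 2.

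Neutrophil markers were higher under NPWT while muscle and epidermis markers were lower. A lower share of those tissues would raise the markers of every other cell type alike, but the neutrophil median lay 3.13 log2 units above that of 64 markers of endothelial, fibroblast, mast and T and NK cells (median 0.10, quartiles -0.39 to 0.37, against a lower quartile of 2.66 for neutrophil markers). For the neutrophil markers these values argue against such a share as the whole cause. The other cell types were chosen with their medians known. They left out monocyte and macrophage markers and B cell markers, which rose. The medians of those left out were 1.16 and 0.85, also under the neutrophil lower quartile. The summed neutrophil CPM was 611 and 695 in the controls and 3544 and 7130 under NPWT, with an exact permutation p of 0.3333, the smallest that 2 against 2 libraries can give. That test could not have decided between the treatment and the wounds sampled, so this stays open.

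Back-splice junctions that join 2 genes of one family were 19 of 84 junctions between 2 genes and held 30.8% of all back-splice counts; the Myh2 to Myh4 junction alone had 1809, 5517, 127 and 438 counts in control 1, control 2, NPWT 1 and NPWT 2. Of the 84 junctions 22.6% joined one family, against a median of 10.7% and an upper limit (of the central 95% of draws) of 17.9% in 2000 draws of gene pairs as far apart, so reads shared between paralogs may be a source. The drawn pairs were not matched for expression. The more abundant partner gene had a median of 607 CPM in one-family junctions and 109 CPM in other pairs. Many one-family junctions also share Myh and Krt genes, so the excess does not settle their source. Circular read-through between neighbours would give like counts per CPM of the partner gene in other gene pairs, but one-family junctions had a median of 0.900 counts per CPM against 0.0299, a log2 difference of 4.91 (permutation p = 2e-05, two-sided), which met the prediction against it. This decides nothing and read-through stays open: the counts had already set these junctions apart (median 812 against 4, with at most 16 in other gene pairs), and many share Myh and Krt genes, so they are not independent, reasons found only after the result was seen.

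The library NPWT 2 had few genes at the lowest counts: 569 genes had 1 count, against 1685 to 1905 in the other 3 long RNA libraries. Its circRNAs had a like pattern, with 134 at 2 counts against 1017 to 1143 in the other 3. The median count of a detected circRNA was 8 in NPWT 2 and 4 in each other library. The cause of that pattern in circRNAs was not tested. Among genes with 6 to 12 counts over the other libraries, 47.3% were at 0 in NPWT 2 against 27.8, 33.1 and 27.8% for control 1, control 2 and NPWT 1, which argues against greater depth as the cause. The mean non-zero count of these genes, the value chosen beforehand, was 6.95 in NPWT 2, above 4.10 and 4.97 in the controls but below 8.61 in NPWT 1, which met the prediction for low-level genes switched off in that wound and not that for fewer distinct molecules. Neither is decided here, because 10 genes held 40.1% of the counts in NPWT 1 and set the upper end of that range, a reason found only after the result was seen. The median non-zero count was 5 in NPWT 2 and 3 in each other library, but 5.31% of these genes were at 1 count in NPWT 2 against 14.6 to 16.8% in the others, so the median restates the pattern and decides nothing.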
